A study of Homo sapiens with 21 samples.

How the data were processed

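RNA of A375 melanoma cells, homozygous for BRAF V600E per the labels, was sequenced in 7 groups of 3 libraries: P4B, P4B_me, BI882370, dabrafenib, vemurafenib and trametinib at 200 nM for 20 h, and the solvent DMSO. Groups and replicate numbers were read from the sample titles, which spell vemurafenib as Vermurafenib. The labels call the libraries triplicates and do not say that they come from separate cultures, so the p-values measure only the spread between these samples.

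Per the labels, RNA was extracted with TRIzol, made into stranded mRNA libraries and sequenced on a NextSeq 500 with 75 cycles. The processing notes list bcl2fastq, FastQC 0.11.5, MultiQC 1.8, TopHat 1.4.1, Bowtie 0.12.7, SAMtools 0.1.18 and the genome build hg19. The program that counted reads per gene, its strand setting and the gene annotation are not given in the sources used here. The deposited matrix holds reads per 1000000 (RPM), made by the authors, for 20314 Ensembl gene identifiers, 1 column per library and 0 columns of no sample. A reference table gave symbols for 19433 of the identifiers and none for 881.

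The values are shortened to 2 decimals without rounding up, and 99.763% to 100% of the low values in each column lie on multiples of 1 step (tolerance, the same shortening). The step puts the depth at 38.3 to 57.2 times 1000000 reads per library: 40.2 to 48.8 for P4B, 46.2 to 54.3 for P4B_me, 39.5 to 49.4 for BI882370, 38.3 to 53.3 for dabrafenib, 45.0 to 50.5 for vemurafenib, 45.0 to 57.2 for trametinib and 50.3 to 56.3 for DMSO. So 1 RPM stands for 38.3 to 57.2 reads and 3 reads for 0.0524 to 0.0783 RPM. The columns sum to 71.86% to 76.61% of 1000000, so the total that the values refer to counts reads outside the listed genes, and the 10 highest genes hold 2.47% to 3.31% of a column. No pair of columns is identical.

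The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from leaving out the third library of all 7 groups, which was added afterwards. The main test was limma 3.58.1 in R 4.3.3 with a trended prior variance on log2(RPM + 1), on 14216 genes with at least 1 RPM in 3 or more of the 21 libraries. All 21 libraries entered as group means with 1 shared spread (14 residual degrees of freedom, median 19.1 in total). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within each of 16 comparisons, 6 against DMSO and 10 between compounds. Fold changes are differences on the log2(RPM + 1) scale, which understates the ratio of genes at low RPM. A change of 2-fold or more means a log2 difference of at least 1 on this scale.

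Genes were named by a rule: a panel of 28 genes (TXNIP had no match), the 8 highest and 8 lowest log2 differences against DMSO, the 6 highest and 6 lowest between compounds, and up to 4 members of each list with the largest changes. The genes with the largest changes needed a mean of at least 5 RPM over the 6 libraries compared and no overlap between the groups, which chance gives for 10% of genes with 3 against 3 libraries. Genes named in 1 comparison may be given in others, and Y-linked genes and XIST were left out. The genes that set P4B apart from the 5 other compounds were chosen after the values were seen.

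The 28 gene lists were written from general knowledge. Of these, 27 were tested, since the mitochondrially encoded transcripts matched 0 identifiers. UHRF1, BOP1, SOD2, ACACA, PSMB3 and PECAM1 also had no match, and EGR2, IL6, TYR, TYRP1, KIT, SOX9 and CCND2 are among the members below the filter. Each list's mean of log2(RPM + 1) per library was tested with limma, adjusted over the 27 lists. Every list was also tested against the other genes with camera, with a preset correlation of 0.01 and with an estimated correlation, and the adjusted p of the latter is given where it ends a call. The MAPK pathway score is such a mean of 10 genes, with a two-sided exact permutation test, whose smallest p is 0.1 with 3 against 3 libraries.

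Agreement between compounds was measured as the correlation and covariance of log2 differences from DMSO across genes, beside 100 simulations of data without group differences that share the DMSO libraries. The 3 DMSO libraries cannot be split between compounds, so part of any excess may come from the shared controls. Expected overlaps are those of independent lists.

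The same replicate number marks libraries that deviate alike: in 12 of 16 comparisons every same-number pair had a correlation of residuals above 0.1, and in the others the lowest was 0.06 to 0.1. The leading component of the residuals (51.9%) sets the third libraries apart. Since nothing in the labels says what the numbers share, they were not used as a block in the main test, and the blocked fit is an alternative. On simulated data with the same design, 33 of 50 genes with a log2 change of 0.25, 47 of 50 with 0.5 and 50 of 50 with 1 were called for P4B against DMSO, with 9 of 13791 unchanged genes called.

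The alternatives were pseudocounts of 0.25 and 5 RPM, no filter, a filter at a mean of 5 RPM, median-of-ratios rescaling, quantile normalization, limma without the trend, only the 6 libraries compared, the replicate block and leaving out each library. GC content and transcript length came from a reference annotation for 98% of the genes tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the steps and drew the plots, and R ran the permutation tests.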

Results

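A375 melanoma cells, homozygous for BRAF V600E per the labels, were treated for 20 h with 1 of 6 compounds at 200 nM or with DMSO, 3 libraries per group. P4B is the BRAF PROTAC and BI882370 the BRAF-binding moiety from which it was made. P4B_me is a methylated P4B that per the labels does not bind the E3 ligase. Dabrafenib and vemurafenib inhibit BRAF, and trametinib inhibits MEK, the kinase that BRAF activates. Gene values are reads per 1000000 (RPM, mean ± SD, n = 3). Log2 differences are differences of mean log2(RPM + 1) with their standard error (SE), and a single number after a gene is this difference. A gene changed, rose or fell where the adjusted p was under 0.05.

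The first principal component held 76.5% of the variance and the second 11.3%. The third (4.4%) set the third library of the groups apart from the others. Correlations across genes ranged from 0.993 to 0.999 between libraries of a group and from 0.884 to 0.998 between groups.

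BRAF mRNA (ENSG00000157764), which encodes the kinase that P4B is directed against, was a little higher than in DMSO under every compound. The log2 difference was 0.38 for P4B, 0.25 for P4B_me and 0.36 for BI882370. It was 0.38 for dabrafenib, 0.30 for vemurafenib and 0.52 for trametinib (SE 0.059), and all 6 passed. P4B did not pass as different from BI882370 in BRAF mRNA (0.019, adjusted p = 0.911). Against P4B_me the difference was 0.12 (adjusted p = 0.122, or 0.0284 with replicate number as a block). BRAF protein, on which a PROTAC acts, is not measured by these libraries. CRBN, which encodes the substrate receptor of a cullin-RING ligase used by many PROTACs, rose with trametinib (0.39, SE 0.11), BI882370 (0.30), vemurafenib (0.28) and dabrafenib (0.25). The last 3 calls ended without the compound's replicate 3 (0.236, 0.199 and 0.182), without DMSO replicate 1 (0.244, 0.221 and 0.196) or 2 (0.254, 0.231 and 0.206) and with median-of-ratios rescaling (0.214, 0.199 and 0.173), for dabrafenib also with no filter or only the 6 libraries compared (0.254). With P4B (0.18, adjusted p = 0.123) and P4B_me (0.21, adjusted p = 0.089) it passed only with the replicate block (adjusted p = 0.007 and 0.00309), without DMSO replicate 3 (0.29 and 0.316), without the third library of all groups (0.176 and 0.29) and, for P4B, without P4B replicate 1 (0.273). The labels do not name the ligase that P4B recruits.

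The MAPK pathway score is the mean log2(RPM + 1) of 10 genes whose transcription follows ERK activity. It was 7.16 ± 0.020 in DMSO, 6.07 ± 0.009 with P4B_me, 5.24 ± 0.083 with BI882370 and 5.17 ± 0.047 with vemurafenib. It was 4.59 ± 0.041 with P4B, 3.38 ± 0.030 with dabrafenib and 2.97 ± 0.061 with trametinib. P4B reached 61.4% of the trametinib fall, BI882370 45.9%, P4B_me 26.1%, vemurafenib 47.6% and dabrafenib 90.4%. The difference of P4B from BI882370 was −0.65 (95% interval −0.72 to −0.57, adjusted p = 1.86e-12). From P4B_me it was −1.48 (−1.55 to −1.41, adjusted p = 2.33e-19), all 3 P4B libraries lying below all 3 of the other group each time.

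BI882370 and vemurafenib did not pass as different in the score (0.071, −0.003 to 0.15, adjusted p = 0.181). They did without BI882370 replicate 3 (0.117, adjusted p = 0.0152) and with a filter at a mean of 5 RPM (0.106). The exact permutation p (two-sided) of the score was 0.3 for that pair. For each other comparison it was 0.1, the smallest that 3 against 3 libraries allow.

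**Figure D1:**
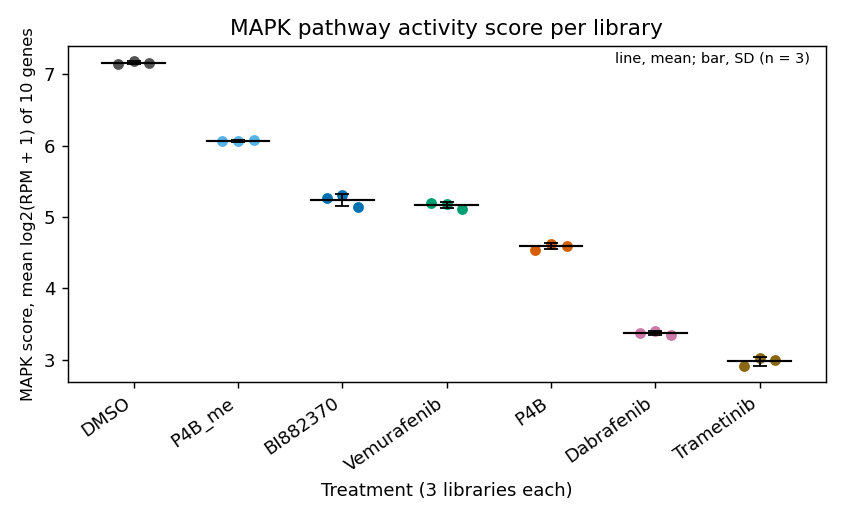
MAPK pathway score (mean log2(RPM + 1) of 10 genes, y axis) of each of 21 libraries by treatment (x axis); lines are means and bars SD of 3 libraries.

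P4B lowered MAPK targets such as SPRY4 and raised DCT and BMF. IGFBP3, which binds insulin-like growth factors, fell to 2.04 ± 0.234 from 173 ± 10.2 RPM (log2 −5.84, SE 0.076). SPRY4, a feedback inhibitor of the pathway induced by ERK, fell to 9.03 ± 0.532 from 308 ± 7.98 RPM (log2 −4.95, SE 0.084). ETV4, an ETS transcription factor downstream of ERK, fell to 10.2 ± 0.61 from 185 ± 8.79 RPM (log2 −4.05, SE 0.081). DCT, a melanin synthesis enzyme, rose to 497 ± 45.4 from 1.09 ± 0.122 RPM (log2 7.89, SE 0.080), with an adjusted p = 3.88e-23. CD36, a fatty acid receptor, rose to 107 ± 16.5 from 0.427 ± 0.199 RPM (log2 6.24, SE 0.11). JUN, an AP-1 subunit, rose to 141 ± 17.3 from 5.14 ± 0.915 RPM (log2 4.53, SE 0.11). BMF, a pro-apoptotic BH3-only protein, rose to 124 ± 8.14 from 6.85 ± 0.321 RPM (log2 3.99, SE 0.055). Libraries did not overlap for these 7 genes, nor for 70.7% of all tested genes. The largest adjusted p of the 7 was 4.98e-18.

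Of 14216 genes tested, 10502 changed, 6011 higher and 4491 lower. By 2-fold or more 1796 changed (1042 higher, 754 lower). The balance of the 2-fold changes rests on the scaling: median-of-ratios rescaling, which shifted the median log2 difference by −0.105, gave 834 higher and 959 lower (4975 and 5435 of any size), and quantile normalization 779 and 852. Among the 8 largest rises were also DLEU7 (4.82), WIPF3 (4.18), an actin regulator, CCN3 (4.10), a matricellular protein, and MOXD1 (4.00). Among the 8 largest falls were CEMIP (−4.65), which degrades hyaluronan, FST (−4.32), an activin antagonist, and EGR1 (−3.92), an immediate early factor. For the lists in this comparison the counts adjusted over the list alone equal those given, which are adjusted over all genes.

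DUSP6, an ERK phosphatase, fell to 24.2 ± 1.81 from 154 ± 0.978 RPM (log2 −2.63, SE 0.061). With it all 10 MAPK score genes fell (0 higher, 10 lower), with a mean difference of −2.58 (95% interval −2.65 to −2.501, adjusted p = 4.21e-24). The other ERK-dependent and immediate early genes fell by 1.10 (95% interval −1.16 to −1.03, adjusted p = 1.55e-18). Among these 36 genes, 4 were higher and 32 lower. IER3 (−3.13), FOSL1 (−3.20), CCND1 (−3.24), which encodes cyclin D1, and MYC (−2.67) were among the falls. The RAS-RAF-MEK-ERK components themselves did not pass in the mean, at −0.005 (95% interval −0.054 to 0.044, adjusted p = 0.843). Among these 26 genes, 11 were higher, 9 lower and 6 not passing. Their median was 0.037, and their mean 0.023 with quantile normalization and −0.115 (adjusted p = 1.23e-05) with median-of-ratios rescaling. RPS6KA1, a kinase downstream of ERK, fell (−0.80) and KSR1, a RAF scaffold, rose (0.52).

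Cell cycle genes fell with P4B, the replication genes most. DNA replication genes fell by 1.35 (95% interval −1.42 to −1.28, adjusted p = 1.53e-19). Among these 37 genes, 0 were higher and 37 lower. MCM10, a replication initiator, fell to 5.97 ± 0.926 from 49.2 ± 0.479 RPM (log2 −2.86, SE 0.088). DTL (−2.60), a CUL4 substrate receptor, and RRM2 (−2.06), a ribonucleotide reductase subunit, fell too. The G1/S regulators fell by 0.89 (95% interval −0.96 to −0.82, adjusted p = 4.85e-16). Among these 25 genes, 5 were higher, 17 lower and 3 not passing, list adjusted p = 0.0901 with an estimated correlation. E2F1 (−2.90) and CDC25A (−2.79), a CDK-activating phosphatase, led this list. Mitosis genes fell by 0.74 (95% interval −0.84 to −0.64, adjusted p = 4.98e-12). Among these 34 genes, 0 were higher, 33 lower and 1 not passing, list adjusted p = 0.113 with an estimated correlation. MAD2L1 (−1.58) of the spindle checkpoint, CDK1 (−1.47) and AURKB (−1.19) were among them. The proliferation marker MKI67 fell (−0.61, SE 0.11) and CDKN1B, a CDK inhibitor, rose (0.34). Ribosome biogenesis genes fell by 0.87 (95% interval −0.91 to −0.82, adjusted p = 3.66e-20). Among these 37 genes, 0 were higher, 34 lower and 3 not passing. LYAR (−1.96) and DKC1 (−1.47), a pseudouridine synthase, had the largest falls here.

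The melanocyte lineage rose in part and most invasive-state genes fell. Melanocyte lineage genes rose by 1.31 (95% interval 1.24 to 1.39, adjusted p = 6.8e-19). Among these 21 genes, 13 were higher, 4 lower and 4 not passing, list adjusted p = 0.239 with an estimated correlation. GPNMB, a melanosomal glycoprotein, rose to 547 ± 28.8 from 74.8 ± 1.36 RPM (log2 2.85, SE 0.060). MITF (2.001, SE 0.074), the lineage's transcription factor, ERBB3 (0.88), SOX10 (0.55) and MLANA (0.52) rose, whereas PMEL, the fibril protein of melanosomes, fell (−1.30). Dedifferentiated or invasive state genes fell by 0.40 (95% interval −0.47 to −0.34, adjusted p = 5.22e-11). Among these 25 genes, 5 were higher, 16 lower and 4 not passing, list adjusted p = 0.205 with an estimated correlation. NT5E (−3.28), an ectonucleotidase, CCN1 (−2.21), EGFR (−1.22) and AXL (−0.45) were lower.

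Receptor tyrosine kinases fell by 0.22 (95% interval −0.28 to −0.16, adjusted p = 2.99e-07). Among these 21 genes, 8 were higher and 13 lower, list adjusted p = 0.447 with an estimated correlation. EPHA4 (−1.69) and EPHA2 (−1.66) fell and PDGFRB (1.43) rose. Extracellular matrix genes rose by 0.47 (95% interval 0.39 to 0.55, adjusted p = 1.92e-10). Among these 24 genes, 16 were higher, 7 lower and 1 not passing, list adjusted p = 0.527 with an estimated correlation. SPP1 (3.66) rose and TIMP3 (−1.69), a metalloprotease inhibitor, fell. Markers of other cell types above the filter rose by 0.59 (95% interval 0.51 to 0.66, adjusted p = 1.99e-12). Among these 11 genes, 8 were higher and 3 lower, list adjusted p = 0.344 with an estimated correlation. CD68, also a lysosomal protein, rose (1.57) and KRT18, a keratin, fell (−1.80). These markers also rose with P4B_me (0.33), BI882370 (0.55), vemurafenib (0.52), dabrafenib (0.65) and trametinib (0.69), each adjusted p = 0.332 or more with an estimated correlation.

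Immune and lysosomal genes moved upward with P4B. Interferon and antigen presentation genes rose by 0.63 (95% interval 0.59 to 0.68, adjusted p = 6.46e-17). Among these 28 genes, 24 were higher, 2 lower and 2 not passing. IRF9, part of the factor that turns on interferon-stimulated genes, rose to 24.8 ± 1.68 from 5.82 ± 0.559 RPM (log2 1.92, SE 0.067), as did its partner STAT2 (1.25). Lysosome and autophagy genes rose by 0.51 (95% interval 0.45 to 0.57, adjusted p = 3.7e-13). Among these 34 genes, 27 were higher, 4 lower and 3 not passing, list adjusted p = 0.194 with an estimated correlation. CTSK (1.41), a cathepsin, and NEU1 (1.18), a sialidase, rose.

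Apoptosis regulators and p53 targets went both ways. BCL2-family genes rose by 0.17 (95% interval 0.12 to 0.22, adjusted p = 3.66e-07). Among these 15 genes, 7 were higher, 5 lower and 3 not passing, list adjusted p = 0.961 with an estimated correlation. Besides BMF, the BH3-only gene BCL2L11 rose (1.10), while PMAIP1 (−2.25) and the anti-apoptotic BCL2 (−1.33) fell. The p53 target genes rose by 0.28 (95% interval 0.24 to 0.33, adjusted p = 5.22e-11). Among these 23 genes, 15 were higher, 6 lower and 2 not passing, list adjusted p = 0.205 with an estimated correlation. TP53INP1 rose (2.41) and AEN, a nuclease, fell (−2.22). FOXO and PI3K-AKT responsive genes rose by 0.37 (95% interval 0.32 to 0.42, adjusted p = 1.61e-12). Among these 21 genes, 12 were higher, 8 lower and 1 not passing, list adjusted p = 0.447 with an estimated correlation. SESN3, a stress sensor, rose (3.02) and TRIB2, a pseudokinase, fell (−2.06).

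Stress and protein quality genes fell. Unfolded protein and integrated stress response genes fell by 0.44 (95% interval −0.48 to −0.40, adjusted p = 6.53e-15). Among these 26 genes, 4 were higher, 17 lower and 5 not passing. MTHFD2, a mitochondrial folate enzyme, fell to 31.6 ± 4.27 from 138 ± 18.5 RPM (log2 −2.09, SE 0.12). ASNS, asparagine synthetase, fell (−1.76) although ATF3 rose (1.44). Heat shock genes fell by 0.73 (95% interval −0.79 to −0.67, adjusted p = 3.13e-16). Among these 16 genes, 1 was higher, 14 lower and 1 not passing. HSPA8, a constitutive chaperone, fell to 478 ± 28.2 from 1561 ± 91.3 RPM (log2 −1.71, SE 0.072). Proteasome subunit genes fell by 0.27 (95% interval −0.32 to −0.22, adjusted p = 9.32e-10). Among these 30 genes, 1 was higher, 25 lower and 4 not passing, list adjusted p = 0.129 with an estimated correlation. PSMD14, a deubiquitinase of the proteasome lid, fell most (−0.75). Cullin-RING ligase components fell by 0.13 (95% interval −0.18 to −0.082, adjusted p = 2.3e-05). Among these 19 genes, 3 were higher, 12 lower and 4 not passing, list adjusted p = 0.194 with an estimated correlation. ELOC (−0.63) and CUL1 (−0.42) were among the falls.

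Aryl hydrocarbon receptor and NRF2 targets did not pass in the mean, at 0.019 (95% interval −0.031 to 0.069, adjusted p = 0.463). Among these 18 genes, 9 were higher, 8 lower and 1 not passing. The camera direction was down although mean and median (0.12) were above 0. Median-of-ratios rescaling turned the mean to −0.089 (adjusted p = 0.00012), and a filter at a mean of 5 RPM gave 0.059 (adjusted p = 0.0219). CYP1B1 (3.27) and CYP1A1 (0.96), enzymes induced by the receptor, rose, and ALDH1A3, which makes retinoic acid, fell (−2.55).

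Glycolysis genes fell by 0.20 (95% interval −0.29 to −0.097, adjusted p = 0.000637). Among these 24 genes, 5 were higher, 13 lower and 6 not passing, list adjusted p = 0.527 with an estimated correlation. PFKFB3, a glycolysis activator, fell (−1.29) and ARRDC4, a glucose uptake regulator, rose (1.28). Oxidative phosphorylation and PGC1 genes did not pass in the mean, at −0.014 (95% interval −0.053 to 0.024, adjusted p = 0.463). Among these 31 genes, 15 were higher, 8 lower and 8 not passing. The median was 0.085, and the mean −0.124 (adjusted p = 9.76e-07) after median-of-ratios rescaling. PPARGC1A rose (0.62) and PPARGC1B fell (−1.30), both coactivators of mitochondrial genes. Fatty acid synthesis genes fell by 0.095 (95% interval −0.15 to −0.042, adjusted p = 0.00168). Among these 11 genes, 2 were higher, 5 lower and 4 not passing, list adjusted p = 0.447 with an estimated correlation. SREBF1, their transcription factor, rose (0.85) and ACSS2, an acetyl-CoA synthetase, fell (−0.80). Housekeeping genes fell by 0.090 (95% interval −0.13 to −0.051, adjusted p = 0.000148). Among these 18 genes, 8 were higher, 7 lower and 3 not passing, list adjusted p = 0.527 with an estimated correlation. Their median was 0.088, and with quantile normalization the adjusted p was 0.0516. TFRC, the transferrin receptor, fell (−1.36), as did ACTB (−0.56).

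Cholesterol synthesis genes fell by 0.051 (95% interval −0.097 to −0.005, adjusted p = 0.0365). Among these 23 genes, 5 were higher, 11 lower and 7 not passing, list adjusted p = 0.239 with an estimated correlation. The call ended without P4B replicate 1 (−0.027) or DMSO replicate 2 (−0.032), with only the 6 libraries compared (adjusted p = 0.149) and with a pseudocount of 0.25 RPM (−0.047). HMGCS1, a synthase early in the pathway, fell (−0.48, SE 0.086).

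Against P4B_me, which does not bind the ligase, P4B had much lower ERK output. SPRY4 was lower, at 9.03 ± 0.532 against 84.9 ± 0.85 RPM (log2 −3.10, SE 0.084, adjusted p = 3.14e-15). ETV5, an ETS factor driven by ERK, was lower, at 10.8 ± 1.64 against 89.5 ± 2.28 RPM (log2 −2.95, SE 0.081). ETV4 (−2.70), CEMIP (−2.40), ITGA9 (−2.16), an integrin subunit, and IGFBP3 (−2.14) were lower as well. CD36 was higher, at 107 ± 16.5 against 20.6 ± 0.317 RPM (log2 2.31, SE 0.11). MAP1LC3C, an autophagy protein, was higher, at 10.4 ± 1.25 against 1.45 ± 0.22 RPM (log2 2.21, SE 0.10). FAM83H, a scaffold of casein kinase 1, was higher, at 29.5 ± 3.91 against 6.9 ± 0.37 RPM (log2 1.94, SE 0.11, adjusted p = 1.11e-10). RAB3B (1.999), a secretory GTPase, DCT (1.97) and ADAMTS15 (1.96), a matrix protease, were also higher. The groups did not overlap for these genes. In this comparison 4429 genes changed, 2474 higher and 1955 lower, and 123 by 2-fold or more (67 higher, 56 lower). The balance turned to 2046 and 2281 with median-of-ratios rescaling and to 2064 and 2214 (2-fold 58 and 61) with quantile normalization.

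The 10 MAPK score genes were all lower (0 higher, 10 lower, and the same adjusted over the list alone). CCND1 (−1.44) and DUSP6 (−1.54) were among them. MYC (−1.85) was lower too, and MITF (0.79) and BMF (1.19) were higher. Ribosome biogenesis genes were lower by 0.41 (95% interval −0.45 to −0.37, adjusted p = 6.22e-14). Of its 37 genes, 0 were higher, 30 lower and 7 not passing (0 higher and 31 lower adjusted over the list alone). Melanocyte lineage genes were higher by 0.48 (95% interval 0.40 to 0.55, adjusted p = 2.03e-10). Of its 21 genes, 10 were higher, 2 lower and 9 not passing (11 higher and 3 lower adjusted over the list alone), list adjusted p = 0.125 with an estimated correlation. The DNA replication genes were lower by 0.28 (95% interval −0.35 to −0.21, adjusted p = 4.97e-07). Of its 37 genes, 1 was higher, 26 lower and 10 not passing (1 higher and 27 lower adjusted over the list alone), list adjusted p = 0.113 with an estimated correlation. Proteasome genes were lower by 0.13 (95% interval −0.18 to −0.077, adjusted p = 9.13e-05). Of its 30 genes, 0 were higher, 11 lower and 19 not passing (0 higher and 13 lower adjusted over the list alone), list adjusted p = 0.13 with an estimated correlation.

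The mitosis genes did not pass in the mean, at −0.079 (95% interval −0.18 to 0.023, adjusted p = 0.143). Of its 34 genes, 0 were higher, 3 lower and 31 not passing (0 higher and 0 lower adjusted over the list alone). They passed as lower without P4B replicate 3 (−0.156, adjusted p = 0.00129), without the third library of all 7 groups (−0.172) and with median-of-ratios rescaling (−0.104). MKI67 did not pass either (−0.071, SE 0.11, adjusted p = 0.662). Cullin-RING components did not pass in the mean, at −0.046 (95% interval −0.094 to 0.003, adjusted p = 0.0872). Of its 19 genes, 0 were higher, 3 lower and 16 not passing (0 higher and 1 lower adjusted over the list alone). They passed with replicate number as a block (adjusted p = 0.0114), without P4B replicate 3 (−0.067), without the third library of all 7 groups (−0.063), and with median-of-ratios rescaling (−0.070) and quantile normalization (−0.051). Markers of other cell types were higher by 0.26 (95% interval 0.18 to 0.34, adjusted p = 4.36e-06). Of its 11 genes, 6 were higher, 1 lower and 4 not passing (7 higher and 2 lower adjusted over the list alone), list adjusted p = 0.184 with an estimated correlation. Housekeeping genes were lower by 0.077 (95% interval −0.12 to −0.038, adjusted p = 0.00102). Of its 18 genes, 0 were higher, 3 lower and 15 not passing (0 higher and 2 lower adjusted over the list alone), list adjusted p = 0.184 with an estimated correlation.

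Against BI882370, the moiety it was built from, P4B had lower MAPK output and higher mitosis genes. TAC1, the tachykinin precursor, was lower, at 11.1 ± 3.32 against 47.8 ± 5.54 RPM (log2 −2.04, SE 0.14, adjusted p = 8.99e-09). ETV5 was lower, at 10.8 ± 1.64 against 38.7 ± 3.29 RPM (log2 −1.76, SE 0.081). SPRY4 was lower, at 9.03 ± 0.532 against 26 ± 3.82 RPM (log2 −1.42, SE 0.084). FST (−1.10), LOXL4 (−0.99), a lysyl oxidase, and XYLT1 (−0.96), a xylosyltransferase, followed. FAM83H was higher, at 29.5 ± 3.91 against 8.52 ± 0.653 RPM (log2 1.68, SE 0.11, adjusted p = 9.06e-09). KIF21B, a kinesin, was higher, at 39.8 ± 4.97 against 15.6 ± 0.767 RPM (log2 1.29, SE 0.086). VWA1, a matrix protein, was higher, at 32 ± 7.28 against 12.4 ± 0.295 RPM (log2 1.27, SE 0.13). MAP1LC3C (1.0), AATK (0.94) and SEMA6B (0.92), a semaphorin, were higher as well. These groups did not overlap for the genes named, nor for 22.6% of those tested.

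Few genes differed between P4B and BI882370: 1102 of 14216 changed, 622 higher and 480 lower, and 9 by 2-fold or more (4 higher, 5 lower). Replicate number as a block gave 2128, leaving out the third library of all groups 2308 and only the 6 libraries compared 693. With median-of-ratios rescaling 491 were higher and 569 lower (2-fold 3 and 6), and with quantile normalization 509 and 599 (2-fold 3 and 8).

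Genes of the mitosis list were higher by 0.52 (95% interval 0.42 to 0.62, adjusted p = 1.57e-08). Of these 34, 32 were higher, 0 lower and 2 not passing (the same adjusted over the list alone). PLK1, a mitotic kinase, was higher, at 93.2 ± 3.78 against 58.2 ± 5.28 RPM (log2 0.67, SE 0.11). ESPL1 (0.72), which encodes separase, AURKB (0.71) and UBE2C (0.69) were higher too. Genes of DNA replication were higher by 0.34 (95% interval 0.27 to 0.41, adjusted p = 2.24e-08). Of these 37, 28 were higher, 0 lower and 9 not passing (36 higher and 0 lower adjusted over the list alone). CDC45 (0.66) and DTL (0.60) led them, and MKI67 was higher (0.59, SE 0.11). G1/S regulators were higher by 0.17 (95% interval 0.097 to 0.24, adjusted p = 0.000551). Of its 25 genes, 9 were higher, 1 lower and 15 not passing (10 higher and 1 lower adjusted over the list alone), list adjusted p = 0.177 with an estimated correlation. E2F2 (0.67) and E2F1 (0.59) were among these.

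Of the MAPK score genes 0 were higher, 7 lower and 3 not passing (0 higher and 7 lower adjusted over the list alone). DUSP6 (−0.75), ETV4 (−0.94) and SPRY2 (−0.88) were lower. The other ERK-dependent genes were lower by 0.16 (95% interval −0.23 to −0.097, adjusted p = 0.000317). Of its 36 genes, 1 was higher, 12 lower and 23 not passing (6 higher and 17 lower adjusted over the list alone). MYC (−0.81) was lower here, and so was the MAPK score gene CCND1 (−0.54). Ribosome biogenesis genes were lower by 0.084 (95% interval −0.12 to −0.044, adjusted p = 0.00155). Of these 37, 0 were higher, 4 lower and 33 not passing (0 higher and 5 lower adjusted over the list alone).

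Small shifts in 4 more lists passed between P4B and BI882370. The p53 target genes were higher by 0.086 (95% interval 0.041 to 0.13, adjusted p = 0.00277). Of its 23 genes, 3 were higher, 1 lower and 19 not passing (8 higher and 2 lower adjusted over the list alone), list adjusted p = 0.177 with an estimated correlation. Fatty acid synthesis genes were higher by 0.083 (95% interval 0.029 to 0.14, adjusted p = 0.0147). Of its 11 genes, 2 were higher, 0 lower and 9 not passing (the same adjusted over the list alone), list adjusted p = 0.227 with an estimated correlation. This call ended without P4B replicate 2 (0.074), without BI882370 replicate 3 (0.069) and with median-of-ratios rescaling (0.060). Heat shock genes were higher by 0.085 (95% interval 0.026 to 0.14, adjusted p = 0.0198). Of its 16 genes, 1 was higher, 0 lower and 15 not passing (the same adjusted over the list alone), list adjusted p = 0.615 with an estimated correlation. It ended without P4B replicate 3 (0.056), BI882370 replicate 3 (0.060) or the third library of all groups (0.031) and with median-of-ratios rescaling (0.063). Dedifferentiated state genes were lower by 0.089 (95% interval −0.15 to −0.025, adjusted p = 0.0238). Of its 25 genes, 1 was higher, 7 lower and 17 not passing (1 higher and 8 lower adjusted over the list alone), list adjusted p = 0.227 with an estimated correlation. It ended without P4B replicate 2 or 3 or BI882370 replicate 1 or 2 (−0.088 to −0.078).

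The following lists did not pass as different between P4B and BI882370. Melanocyte lineage genes did not pass in the mean, at −0.029 (95% interval −0.10 to 0.045, adjusted p = 0.712). Of these 21, 2 were higher, 3 lower and 16 not passing (3 higher and 4 lower adjusted over the list alone). Yet PMEL was higher in P4B (0.28), and BMF did not pass (−0.035, SE 0.055, adjusted p = 0.803). Proteasome subunits did not pass in the mean, at −0.018 (95% interval −0.069 to 0.033, adjusted p = 0.736). Of these 30, 0 were higher, 1 lower and 29 not passing (0 higher and 0 lower adjusted over the list alone). Interferon genes did not pass in the mean, at −0.015 (95% interval −0.061 to 0.031, adjusted p = 0.747). Of its 28 genes, 1 was higher, 2 lower and 25 not passing (2 higher and 3 lower adjusted over the list alone). Lysosome genes did not pass in the mean, at −0.019 (95% interval −0.079 to 0.042, adjusted p = 0.747). Of its 34 genes, 1 was higher, 0 lower and 33 not passing (0 higher and 0 lower adjusted over the list alone). Cullin-RING components, which a degrader depends on, had a mean difference of −0.003 (95% interval −0.051 to 0.046, adjusted p = 0.985).

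**Figure D2:**
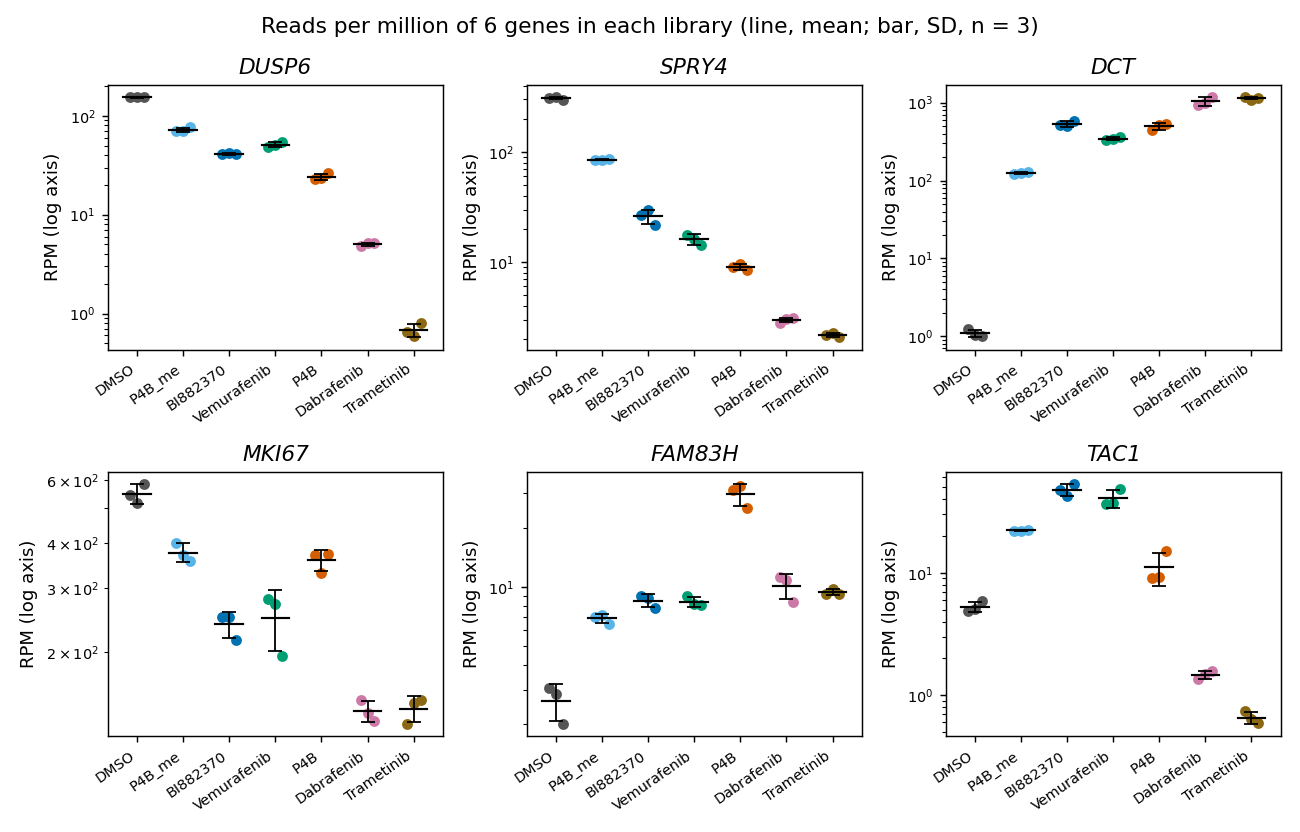
RPM (log axis) of DUSP6, SPRY4, DCT, MKI67, FAM83H and TAC1 in each of 21 libraries by treatment; lines are means and bars SD of 3 libraries.

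P4B_me lowered MAPK output less than BI882370 did. ETV4 was higher, at 71.8 ± 0.925 against 20.6 ± 2.51 RPM (log2 1.76, SE 0.081). SPRY4 was higher, at 84.9 ± 0.85 against 26 ± 3.82 RPM (log2 1.68, SE 0.084). MCM10 (1.47), CEMIP (1.57), DTL (1.30) and CCND1 (0.91) were higher too. CD36 was lower, at 20.6 ± 0.317 against 140 ± 13.7 RPM (log2 −2.70, SE 0.11). DCT was lower, at 126 ± 4.73 against 537 ± 44.3 RPM (log2 −2.08, SE 0.080, adjusted p = 1.11e-12). PRUNE2 (−2.13), a BCH-domain protein, ATF3 (−1.75), a stress-induced factor, CCN3 (−1.70) and BMF (−1.23) were lower. None overlapped. Between these compounds 3987 genes changed (2074 higher, 1913 lower), 78 by 2-fold or more (25 higher, 53 lower).

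MAPK score genes were higher by 0.83 (95% interval 0.76 to 0.90, adjusted p = 1.77e-14). Among these 10 genes, 9 were higher, 0 lower and 1 not passing (10 higher and 0 lower adjusted over the list alone). Replication genes were higher by 0.62 (95% interval 0.55 to 0.69, adjusted p = 7.83e-13). Among the 37, 36 were higher and 1 lower (the same adjusted over the list alone). Genes of mitosis were higher by 0.60 (95% interval 0.50 to 0.70, adjusted p = 5.43e-10). Among the 34, 33 were higher, 0 lower and 1 not passing (the same adjusted over the list alone). Melanocyte lineage genes were lower by 0.51 (95% interval −0.58 to −0.43, adjusted p = 5.2e-11). Among the 21, 2 were higher, 11 lower and 8 not passing (the same adjusted over the list alone). Markers of other cell types were lower by 0.23 (95% interval −0.30 to −0.15, adjusted p = 1.1e-05). Of these 11, 2 were higher, 6 lower and 3 not passing (2 higher and 8 lower adjusted over the list alone), list adjusted p = 0.21 with an estimated correlation. They did not pass with a filter at a mean of 5 RPM (−0.089).

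**Figure D3:**
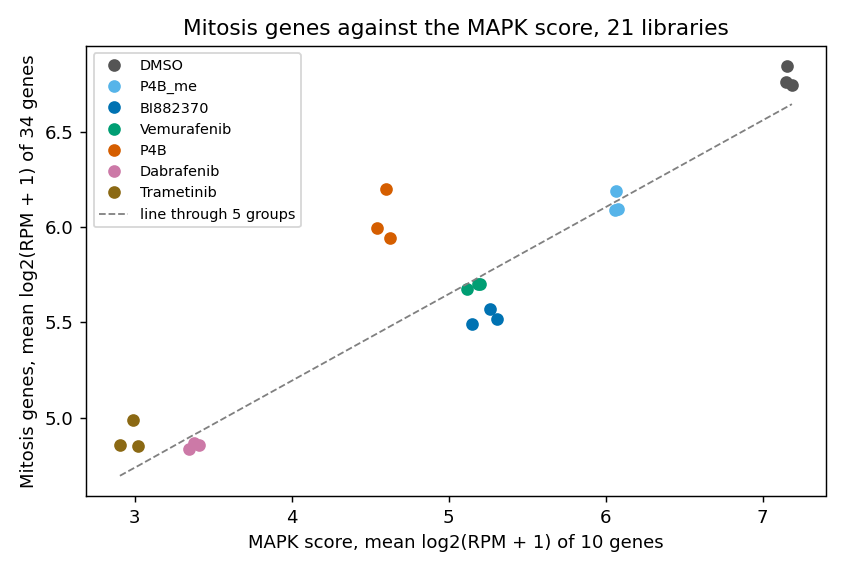
Mean log2(RPM + 1) of 34 mitosis genes (y axis) against the MAPK pathway score (x axis) for 21 libraries, with the line (slope 0.455) through the 15 libraries of DMSO, BI882370, vemurafenib, dabrafenib and trametinib.

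P4B and vemurafenib, a BRAF inhibitor in clinical use, differed in few genes. TAC1 was lower, at 11.1 ± 3.32 against 40.5 ± 6.48 RPM (log2 −1.80, SE 0.14, adjusted p = 4.71e-08). ETV5 was lower, at 10.8 ± 1.64 against 32.3 ± 1.95 RPM (log2 −1.51, SE 0.081). DUSP6 was lower, at 24.2 ± 1.81 against 51.1 ± 3.11 RPM (log2 −1.05, SE 0.061). SAT1 (−1.10), a polyamine-degrading enzyme, FST (−0.999) and LRATD2 (−0.96) were lower too. FAM83H was higher, at 29.5 ± 3.91 against 8.38 ± 0.488 RPM (log2 1.70, SE 0.11, adjusted p = 9.03e-09). MAP1LC3C (1.52), VWA1 (1.26), RAB3B (1.24), KIF21B (1.23) and ADAMTS15 (0.95) were higher, without overlap for any of these genes.

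In this pair 1148 genes changed (711 higher, 437 lower), 12 by 2-fold or more (5 higher, 7 lower). The balance turned to 499 higher and 537 lower with median-of-ratios rescaling and to 487 and 594 with quantile normalization. The replicate block gave 2433 genes, only the 6 libraries compared 321, leaving out vemurafenib replicate 3 gave 688, vemurafenib replicate 2 755 and P4B replicate 2 735. Genes of the MAPK score were lower by 0.58 (95% interval −0.65 to −0.50, adjusted p = 1.64e-11). Of its 10 genes, 0 were higher, 6 lower and 4 not passing (the same adjusted over the list alone). Mitosis genes were higher by 0.35 (95% interval 0.25 to 0.46, adjusted p = 7.18e-06). By gene, of 34, 23 were higher, 0 lower and 11 not passing (31 higher and 0 lower adjusted over the list alone), list adjusted p = 0.0524 with an estimated correlation. The DNA replication genes were higher by 0.15 (95% interval 0.082 to 0.22, adjusted p = 0.00116). By gene, of 37, 3 were higher, 0 lower and 34 not passing (12 higher and 0 lower adjusted over the list alone), list adjusted p = 0.291 with an estimated correlation. The other ERK-dependent genes did not pass in the mean, at 0.007 (95% interval −0.059 to 0.072, adjusted p = 0.941). Of these 36, 6 were higher, 8 lower and 22 not passing (11 higher and 10 lower adjusted over the list alone). This mean turned to −0.018 with median-of-ratios rescaling and −0.024 with quantile normalization.

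Dabrafenib at the same dose and time lowered MAPK output and proliferation genes further than P4B. SH3TC2, an endosomal protein, was higher, at 38.9 ± 3.26 against 5.05 ± 0.465 RPM (log2 2.72, SE 0.069). TFAP2B, a transcription factor, was higher, at 253 ± 17.4 against 41.5 ± 1.48 RPM (log2 2.58, SE 0.055). DUSP6 was higher, at 24.2 ± 1.81 against 5.04 ± 0.185 RPM (log2 2.06, SE 0.061). ETV5 (2.03), TAC1 (2.26) and COL8A1 (2.09) were higher with P4B too. FOS, an immediate early AP-1 subunit, was lower, at 4.3 ± 0.672 against 19.3 ± 0.119 RPM (log2 −1.94, SE 0.075, adjusted p = 3.71e-13). PRUNE2 (−1.81) and DCT (−1.06) were lower, without overlap for any of these genes.

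Here 4813 genes changed (2889 higher, 1924 lower), 225 by 2-fold or more (160 higher, 65 lower). Quantile normalization turned the balance to 2321 higher and 2562 lower, and with only the 6 libraries compared 2887 changed. The mitosis genes were higher by 1.19 (95% interval 1.09 to 1.29, adjusted p = 3.73e-15). Of the 34 genes, 34 were higher and 0 lower (the same adjusted over the list alone). ASPM (1.55), a spindle pole protein, and MKI67 (1.38) were among those higher with P4B. Genes of DNA replication were higher by 0.72 (95% interval 0.66 to 0.80, adjusted p = 2.72e-14). Of the 37 genes, 34 were higher, 2 lower and 1 not passing (35 higher and 2 lower adjusted over the list alone). The MAPK score genes were higher by 1.21 (95% interval 1.14 to 1.29, adjusted p = 1.15e-17). Of these 10, 9 were higher, 0 lower and 1 not passing (the same adjusted over the list alone).

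The MEK inhibitor trametinib acted further still on ERK feedback genes. DUSP6 was higher, at 24.2 ± 1.81 against 0.68 ± 0.108 RPM (log2 3.90, SE 0.061, adjusted p = 1.47e-19). SH3TC2 was higher, at 38.9 ± 3.26 against 1.53 ± 0.157 RPM (log2 3.98, SE 0.069). SPRY2, a feedback inhibitor, was higher, at 32 ± 1.74 against 5.11 ± 0.586 RPM (log2 2.44, SE 0.062). TFAP2B (3.38), TAC1 (2.83) and C10orf90 (2.65), a p53 regulator, were higher as well. FOS was lower, at 4.3 ± 0.672 against 28.4 ± 0.48 RPM (log2 −2.48, SE 0.075). ATF3 (−2.31), PRUNE2 (−2.23) and DCT (−1.20) were lower, without overlap for any of these genes.

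Between P4B and trametinib 5343 genes changed (3031 higher, 2312 lower), 318 by 2-fold or more (194 higher, 124 lower), and with quantile normalization 2627 higher and 2715 lower. MAPK score genes were higher by 1.62 (95% interval 1.54 to 1.69, adjusted p = 4.12e-20). Among the 10, 9 were higher, 0 lower and 1 not passing (the same adjusted over the list alone). Genes of the mitosis list were higher by 1.15 (95% interval 1.05 to 1.25, adjusted p = 7.69e-15). Among these 34 genes, 34 were higher and 0 lower (the same adjusted over the list alone). Replication genes were higher by 0.71 (95% interval 0.64 to 0.78, adjusted p = 3.96e-14). Among these 37 genes, 34 were higher, 2 lower and 1 not passing (35 higher and 2 lower adjusted over the list alone).

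P4B_me was itself active against DMSO. DCT rose to 126 ± 4.73 from 1.09 ± 0.122 RPM (log2 5.92, SE 0.080, adjusted p = 9.06e-21). CD36 rose to 20.6 ± 0.317 from 0.427 ± 0.199 RPM (log2 3.93, SE 0.11). DLEU7 (3.70) and MGP (3.53), a matrix Gla protein, rose too. IGFBP3 fell to 12.4 ± 0.629 from 173 ± 10.2 RPM (log2 −3.70, SE 0.076). EGR1 (−3.04), INHBA (−2.64), an activin subunit, NT5E (−2.38), SPRY4 (−1.85), CCND1 (−1.80) and DUSP6 (−1.08) fell, without overlap of the 3 and 3 libraries. P4B_me changed 9216 genes, 5272 higher and 3944 lower, but 4303 and 4950 with median-of-ratios rescaling. By 2-fold or more 842 changed (463 higher, 379 lower), but 392 and 471 with that rescaling and 355 and 409 with quantile normalization. The DNA replication genes fell by 1.07 (95% interval −1.15 to −1.005, adjusted p = 4.12e-17). Of its 37 genes, 0 were higher and 37 lower (the same adjusted over the list alone). Genes of mitosis fell by 0.66 (95% interval −0.76 to −0.56, adjusted p = 4.58e-11). Of its 34 genes, 0 were higher, 33 lower and 1 not passing (the same adjusted over the list alone), list adjusted p = 0.0732 with an estimated correlation.

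BI882370 raised and lowered many of the genes that P4B did. DCT rose to 537 ± 44.3 from 1.09 ± 0.122 RPM (log2 8.01, SE 0.080, adjusted p = 2.96e-23). CD36 (6.63), JUN (4.42) and BMF (4.02) rose too. SPRY4 fell to 26 ± 3.82 from 308 ± 7.98 RPM (log2 −3.53, SE 0.084). IGFBP3 (−4.87), CEMIP (−3.82), E2F1 (−3.49) and DUSP6 (−1.88) fell, without overlap with DMSO. The genes changed numbered 10483 (5863 higher, 4620 lower), 1897 by 2-fold or more (1015 higher, 882 lower). This balance turned with median-of-ratios rescaling (5004 higher and 5401 lower, 2-fold 841 and 1028) and, for 2-fold, with quantile normalization (806 and 939). Genes of DNA replication fell by 1.70 (95% interval −1.77 to −1.63, adjusted p = 2.72e-21). Of these 37, 0 were higher and 37 lower (the same adjusted over the list alone). Mitosis genes fell by 1.26 (95% interval −1.36 to −1.16, adjusted p = 3e-16). Of these 34, 0 were higher, 33 lower and 1 not passing (the same adjusted over the list alone).

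Vemurafenib acted on the same markers. DCT rose to 347 ± 15.2 from 1.09 ± 0.122 RPM (log2 7.38, SE 0.080, adjusted p = 1.4e-22). CD36 (5.93) and JUN (4.28) rose too. SPRY4 fell to 16 ± 1.77 from 308 ± 7.98 RPM (log2 −4.19, SE 0.084). IGFBP3 (−5.21), CEMIP (−4.56) and DUSP6 (−1.57) fell, without overlap of the 3 and 3 libraries. Vemurafenib changed 10373 genes (5657 higher, 4716 lower), 1781 by 2-fold or more (949 higher, 832 lower). With median-of-ratios rescaling the balance turned to 4906 and 5457 (2-fold 807 and 995), and with quantile normalization 2-fold to 760 and 892. Replication genes fell by 1.505 (95% interval −1.57 to −1.44, adjusted p = 2.84e-20). Among the 37, 0 were higher and 37 lower (the same adjusted over the list alone). The mitosis genes fell by 1.09 (95% interval −1.19 to −0.99, adjusted p = 4.11e-15). Among the 34, 0 were higher and 34 lower (the same adjusted over the list alone), list adjusted p = 0.0564 with an estimated correlation.

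Dabrafenib had larger effects on these genes. DCT rose to 1038 ± 127 from 1.09 ± 0.122 RPM (log2 8.95, SE 0.080, adjusted p = 3.53e-24). PRUNE2 (5.69), JUN (5.38), BMF (4.79) and SEMA3C (4.41), a secreted semaphorin, rose too. DUSP6 fell to 5.04 ± 0.185 from 154 ± 0.978 RPM (log2 −4.68, SE 0.061). SPRY4 (−6.28), FST (−5.51), ETV4 (−5.41) and ETV5 (−5.29) fell, again without overlap. Dabrafenib changed 11136 genes (5944 higher, 5192 lower), 2866 by 2-fold or more (1502 higher, 1364 lower). Median-of-ratios rescaling turned this to 5331 and 5785 (2-fold 1332 and 1549), and quantile normalization turned 2-fold to 1270 and 1413. The DNA replication genes fell by 2.08 (95% interval −2.15 to −2.01, adjusted p = 4.91e-23). By gene, of 37, 0 were higher and 37 lower (the same adjusted over the list alone). Genes of the mitosis list fell by 1.93 (95% interval −2.03 to −1.83, adjusted p = 1.07e-19). By gene, of 34, 0 were higher and 34 lower (the same adjusted over the list alone).

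Trametinib changed most genes, 11197 (6105 higher, 5092 lower), 2983 by 2-fold or more (1595 higher, 1388 lower). These turned to 5322 and 5822 (2-fold 1369 and 1604) with median-of-ratios rescaling, and 2-fold to 1304 and 1448 with quantile normalization. DCT rose to 1142 ± 40.1 from 1.09 ± 0.122 RPM (log2 9.10, SE 0.080, adjusted p = 2.61e-24). CD36 (7.29), PRUNE2 (6.11), JUN (5.73), BMF (5.00) and ATF3 (3.75) rose too. DUSP6 fell to 0.68 ± 0.108 from 154 ± 0.978 RPM (log2 −6.53, SE 0.061). SPRY4 (−6.62), FST (−5.63), ETV4 (−5.53) and LRATD2 (−5.07) fell, also without overlap. Genes of DNA replication fell by 2.06 (95% interval −2.13 to −1.99, adjusted p = 5.61e-23). Of the 37 genes, 1 was higher and 36 lower (the same adjusted over the list alone). Genes of mitosis fell by 1.89 (95% interval −1.99 to −1.78, adjusted p = 1.45e-19). Of the 34 genes, 0 were higher and 34 lower (the same adjusted over the list alone).

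BI882370 and vemurafenib were close. PRUNE2 was higher, at 49 ± 3.23 against 25.8 ± 2.48 RPM (log2 0.90, SE 0.072, adjusted p = 8.06e-07). UCN2 (0.83), a corticotropin-family peptide, IL24 (0.71), CD36 (0.70), SPRY4 (0.66) and DCT (0.63) were higher with BI882370. CCN1 (−0.62), a matricellular protein, was lower, again without overlap of 3 and 3 libraries. By limma 191 genes changed (148 higher, 43 lower) and 0 by 2-fold or more, while 1400 had an unadjusted p under 0.05. The count was 486 with the replicate block, 102 with only the 6 libraries compared and 126 without the third library of all groups. It was 117, 125 and 90 without BI882370 replicates 1, 2 and 3, and 109 and 97 without vemurafenib replicates 2 and 3.

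Replication genes were lower by 0.19 (95% interval −0.26 to −0.12, adjusted p = 0.000395). Among these 37 genes, 0 were higher, 2 lower and 35 not passing (0 higher and 21 lower adjusted over the list alone). Mitosis genes were lower by 0.17 (95% interval −0.27 to −0.064, adjusted p = 0.0192). Among these 34 genes, 0 were higher, 3 lower and 31 not passing (0 higher and 14 lower adjusted over the list alone), list adjusted p = 0.0835 with an estimated correlation. This call ended without BI882370 replicate 2 or 3 or vemurafenib replicate 1 or 2 (−0.162 to −0.149). The other ERK-dependent genes were higher by 0.17 (95% interval 0.10 to 0.24, adjusted p = 0.000395). Among the 36, 5 were higher, 0 lower and 31 not passing (8 higher and 0 lower adjusted over the list alone). Melanocyte lineage genes were higher by 0.17 (95% interval 0.094 to 0.24, adjusted p = 0.00123). By gene, of 21, 3 were higher, 0 lower and 18 not passing (7 higher and 0 lower adjusted over the list alone), list adjusted p = 0.102 with an estimated correlation.

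BI882370 left ERK targets higher than dabrafenib did. TAC1 was higher, at 47.8 ± 5.54 against 1.47 ± 0.12 RPM (log2 4.30, SE 0.14, adjusted p = 5.24e-15). ETV5 was higher, at 38.7 ± 3.29 against 1.87 ± 0.0945 RPM (log2 3.79, SE 0.081). DUSP6 (2.80), SH3TC2 (3.28), TFAP2B (3.19) and LRATD2 (2.84) were higher too. MYRF, a membrane-bound transcription factor, was lower, at 17 ± 0.301 against 72.1 ± 7.35 RPM (log2 −2.02, SE 0.079). FOSL2 (−1.78), an AP-1 subunit, RAB3B (−1.73), ADAMTS15 (−1.71) and FOS (−1.60) were lower, with no overlap of 3 and 3 libraries. The comparison gave 4769 changed genes (2620 higher, 2149 lower), 183 by 2-fold or more (124 higher, 59 lower), and with quantile normalization 2317 higher and 2488 lower. Genes of the MAPK score were higher by 1.86 (95% interval 1.79 to 1.94, adjusted p = 2.53e-21). By gene, of 10, 9 were higher, 0 lower and 1 not passing (the same adjusted over the list alone). The mitosis genes were higher by 0.67 (95% interval 0.57 to 0.77, adjusted p = 1.14e-10). Of its 34 genes, 32 were higher, 0 lower and 2 not passing (34 higher and 0 lower adjusted over the list alone). The DNA replication genes were higher by 0.38 (95% interval 0.31 to 0.45, adjusted p = 1.69e-09). Of its 37 genes, 26 were higher, 2 lower and 9 not passing (29 higher and 2 lower adjusted over the list alone), list adjusted p = 0.0843 with an estimated correlation.

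The marketed BRAF inhibitors dabrafenib and vemurafenib differed widely at this dose. FOSL2 was higher, at 93.3 ± 4.48 against 18.7 ± 1.17 RPM (log2 2.26, SE 0.067, adjusted p = 2.04e-15). RAB3B (2.22), PRUNE2 (2.20) and MYRF (2.20) were higher with dabrafenib too. TAC1 was lower, at 1.47 ± 0.12 against 40.5 ± 6.48 RPM (log2 −4.06, SE 0.14). DUSP6 was lower, at 5.04 ± 0.185 against 51.1 ± 3.11 RPM (log2 −3.11, SE 0.061). ETV5 (−3.53), TFAP2B (−3.21), MYC (−1.75) and CCND1 (−1.22) were lower, without overlap of 3 and 3 libraries. Between the pair 5347 genes changed (2562 higher, 2785 lower), 277 by 2-fold or more (121 higher, 156 lower), and with quantile normalization 2754 higher and 2641 lower. The MAPK score genes were lower by 1.79 (95% interval −1.86 to −1.72, adjusted p = 5.47e-21). Of the 10 genes, 0 were higher, 9 lower and 1 not passing (the same adjusted over the list alone). Genes of the mitosis list were lower by 0.84 (95% interval −0.94 to −0.74, adjusted p = 2.28e-12). Of these 34, 0 were higher, 33 lower and 1 not passing (the same adjusted over the list alone). Genes of DNA replication were lower by 0.57 (95% interval −0.64 to −0.50, adjusted p = 2.28e-12). Of these 37, 2 were higher, 31 lower and 4 not passing (2 higher and 33 lower adjusted over the list alone).

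PHGDH, ASNS and DUSP6 were among the genes that differed between dabrafenib and trametinib. PHGDH, the first enzyme of serine synthesis, was higher, at 187 ± 25.9 against 85.8 ± 2.69 RPM (log2 1.11, SE 0.082, adjusted p = 4.57e-08). ASNS was higher, at 46.4 ± 1.91 against 23.4 ± 1.18 RPM (log2 0.96, SE 0.061). DUSP6 was higher, at 5.04 ± 0.185 against 0.68 ± 0.108 RPM (log2 1.85, SE 0.061). CBS (0.94), a transsulfuration enzyme, ALDH1L2 (0.92), a mitochondrial folate enzyme, SPRY2 (0.87), TFAP2B (0.80) and ATF4 (0.47), which drives amino acid synthesis genes, were also higher with dabrafenib. MAP1LC3C (−0.84), ATF3 (−0.71) and CD36 (−0.71) were lower, without overlap for any of these genes. Of the genes tested 223 changed (128 higher, 95 lower), 5 of them by 2-fold or more, 5 higher and 0 lower by limma, with 1561 genes at an unadjusted p under 0.05. The count was 619 with the replicate block, 131 without dabrafenib replicate 2, 137 without trametinib replicate 1, 73 with only the 6 libraries compared and 968 without the third library of all groups.

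MAPK score genes were higher by 0.40 (95% interval 0.33 to 0.48, adjusted p = 1.05e-08). Among these 10 genes, 4 were higher, 0 lower and 6 not passing (5 higher and 0 lower adjusted over the list alone). Unfolded protein and integrated stress response genes were higher by 0.097 (95% interval 0.056 to 0.14, adjusted p = 0.00124). Of its 26 genes, 5 were higher, 1 lower and 20 not passing (6 higher and 2 lower adjusted over the list alone), list adjusted p = 0.119 with an estimated correlation. Their median was −0.005. Replication genes did not pass in the mean, at −0.014 (95% interval −0.084 to 0.056, adjusted p = 0.848). Among the 37, 0 were higher, 1 lower and 36 not passing (the same adjusted over the list alone). This mean turned to 0.003 with median-of-ratios rescaling and 0.011 with quantile normalization. Genes of mitosis did not pass in the mean, at −0.044 (95% interval −0.15 to 0.058, adjusted p = 0.638). Among the 34, 0 were higher, 0 lower and 34 not passing (the same adjusted over the list alone).

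The responses to the compounds ran in the same direction across genes. Of 15 pairs of compounds compared, 8 are given here, each over 14216 genes, which are not independent replicates. The correlation of the log2 differences from DMSO was 0.946 for P4B with P4B_me (covariance 0.348), 0.975 with BI882370 (0.491) and 0.976 with vemurafenib (0.48). It was 0.958 with dabrafenib (0.605) and 0.949 with trametinib (0.617). Between other compounds it was 0.966 for P4B_me with BI882370 (0.36), 0.989 for BI882370 with vemurafenib (0.492) and 0.992 for dabrafenib with trametinib (0.818). In the 7 other pairs it ran from 0.866 for P4B_me with trametinib to 0.975 for P4B_me with vemurafenib. All pairs share the 3 DMSO libraries, which alone gave a correlation of 0.5 and a covariance of 0.004 in 100 simulations without any difference between groups.

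Genes that rose or fell 2-fold or more were largely common to the compounds. P4B and BI882370 shared 875 higher genes, against 74.4 for independent lists, and 670 lower genes, against 46.8. P4B and P4B_me shared 427 (33.9) and 359 (20.1), and P4B and vemurafenib 842 (69.6) and 672 (44.1). With dabrafenib P4B shared 963 (110.1) and 722 (72.3), and with trametinib 962 (116.9) and 716 (73.6). P4B_me and BI882370 shared 448 (33.1) and 372 (23.5). BI882370 and vemurafenib shared 880 (67.8) and 775 (51.6), and dabrafenib and trametinib 1418 (168.5) and 1284 (133.2). In each of these 8 pairs 0 genes passed 2-fold in opposite directions by limma, and 1 or 2 did in 6 of the 7 other pairs.

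P4B differed from all 5 other compounds in the same direction in 44 higher and 14 lower genes. The 0 of 100 simulations without group differences is no yardstick, as the compounds differ. The counts were 30 and 20 with median-of-ratios rescaling, 34 and 25 with quantile normalization, 132 and 31 with the replicate block and 126 and 23 without the third library of all groups. They were 33 and 7, 28 and 10, and 69 and 22 without P4B replicates 1, 2 and 3. FAM83H had the largest difference, 1.68 from BI882370, 1.94 from P4B_me, 1.46 from dabrafenib, 1.70 from vemurafenib and 1.54 from trametinib. SHISAL1 (−0.96 from BI882370), and TK2, a mitochondrial thymidine kinase (−0.35), were among the lower ones. These genes were chosen after the values were seen. Genes higher in P4B than in both BI882370 and P4B_me numbered 246, against 108.2 for independent lists, and genes lower than in both 305, against 66. Both differences contain the same P4B libraries: their correlation across genes was 0.433, with 0.501 in simulations without a difference, and their covariance 0.0187, with 0.004. In both 551 genes passed.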

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

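Leaving out the third library of all 7 groups was an alternative chosen after the data were seen. Over 16 comparisons, 234 of 256 alternatives kept a count of changed genes within 1.5 times, 233 of 256 a 2-fold count, and 254 of 256 a MAPK score call. For list means 6354 of 6656 kept the call (148 of these, past the threshold in neither fit, changed sign), 108 gained a call, 181 lost one and 13 reversed with a call. With camera 503 of 864 list calls held, 357 were lost and 4 gained. Of the alternatives for named genes, 4764 of 4825 kept the call (6 not past the threshold changed sign), 53 lost the call, 8 gained one and 0 reversed. These include named genes left out of the text since at least 1 alternative changed their call: CD36, CDT1 and MITF for P4B against BI882370, SCIN against P4B_me, TIPARP against dabrafenib, CENPE, MKI67 and SHISA2 against vemurafenib, FASN against DMSO, and DUSP6, UNC5C and CDC45 for BI882370 against vemurafenib. Among named genes the replicate block changed only the calls of BRAF for P4B against P4B_me and CRBN for P4B and P4B_me against DMSO. The cause of the changes was not tested unless given. A higher pseudocount shrinks log2 differences by construction, and with only 6 libraries the spread rests on fewer libraries. Leaving out 1 library leaves 2 in a group. edgeR and DESeq2 on recovered reads were not run. Genes under 0.0524 to 0.0783 RPM rest on 3 reads or fewer, which limits what the depth can show.

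Counts of changed genes moved as follows. BI882370 against vemurafenib (191) gave 486 with the replicate block, 126 without the third libraries, 102 with only the 6 libraries and 90 to 153 on leaving out 1 library, lowest without BI882370 replicate 3. Dabrafenib against trametinib (223) gave 619, 968, 73 and 131 to 333, lowest without dabrafenib replicate 2. P4B against BI882370 (1102) gave 2128, 2308, 693 and 738 to 1236, lowest without BI882370 replicate 3. P4B against vemurafenib (1148) gave 2433 with the block, 321 with only the 6 libraries and 688 to 1120 on leaving out 1, lowest without vemurafenib replicate 3. P4B against dabrafenib (4813) gave 2887 with only the 6 libraries.

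Counts of 2-fold changes with a pseudocount of 0.25 RPM were 298 for BI882370 against dabrafenib, 10 for dabrafenib against trametinib, 425 for dabrafenib against vemurafenib, 18 for P4B against BI882370, 345 against dabrafenib, 201 against P4B_me and 130 for P4B_me against BI882370. With 5 RPM they were 83 for BI882370 against dabrafenib, 1 for dabrafenib against trametinib, 115 for dabrafenib against vemurafenib, 92 for P4B against dabrafenib, 53 against P4B_me, 146 against trametinib, 5 against vemurafenib, and 25 for P4B_me against BI882370. Against DMSO they were 917 for P4B, 405 for P4B_me, 1043 for BI882370, 1689 for dabrafenib, 952 for vemurafenib and 1767 for trametinib. A filter at a mean of 5 RPM, with fewer genes tested, gave 3 for dabrafenib against trametinib, and leaving out the third libraries gave 16 for P4B against BI882370.

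The MAPK score of BI882370 minus vemurafenib passed at 0.106 with a filter at a mean of 5 RPM and ranged from 0.037 to 0.117 on leaving out 1 library, passing without BI882370 replicate 3. Median-of-ratios rescaling reversed list means against DMSO: aryl hydrocarbon receptor and NRF2 targets to −0.089 for P4B, −0.007 for BI882370, −0.020 for dabrafenib, −0.037 for trametinib and −0.051 for vemurafenib, and for P4B_me the BCL2 family to −0.059, cholesterol synthesis to −0.032, fatty acid synthesis to −0.081 and oxidative phosphorylation to −0.050. Quantile normalization turned housekeeping genes with vemurafenib to 0.002. The filter at a mean of 5 RPM turned markers of other cell types to 0.069 for BI882370 against dabrafenib, −0.051 for dabrafenib against vemurafenib and 0.115 for P4B against trametinib.

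Covariances between compounds with pseudocounts of 0.25 and 5 RPM were 0.454 and 0.212 for P4B with P4B_me, 0.637 and 0.3 with BI882370, 0.624 and 0.293 with vemurafenib, 0.785 and 0.369 with dabrafenib and 0.802 and 0.376 with trametinib. They were 0.467 and 0.219 for P4B_me with BI882370, 0.637 and 0.3 for BI882370 with vemurafenib and 1.063 and 0.496 for dabrafenib with trametinib. The last was 0.826 with median-of-ratios rescaling and 0.819 to 0.826 on leaving out 1 DMSO library. With a filter at a mean of 5 RPM the correlation was 0.961 for P4B with dabrafenib, 0.95 with P4B_me and 0.97 for P4B_me with BI882370.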

Other observations

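The tests of pathway strength and ligase binding for the mitosis genes, of dabrafenib against vemurafenib and of GC content without the block for the genes that set P4B apart and of weaker inhibition for the ATF4 targets were chosen after the result was seen. So were the 2 lists in the last pattern, which are parts of the list of unfolded protein and integrated stress response genes.

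Mitosis genes were higher in P4B than in BI882370 although the MAPK score was lower, by 0.52 in the mean (95% interval of a plain linear model 0.401 to 0.639, 34 genes). Strength of pathway inhibition alone, with mitosis genes following the score, is argued against by this sign, which is also the observation that prompted the test. Technical explanations were argued against: the difference was 0.498 with median-of-ratios rescaling, 0.443 without P4B replicate 3, the lowest of the 6 libraries left out, and 0.52 with the trend on GC content and transcript length removed and the replicate block. The 3 P4B libraries lay at least 0.465 above the line of mitosis genes on the MAPK score through the 15 libraries of the other 5 groups and P4B_me between −0.047 and 0.055, but the BI882370 libraries lay 0.198 to 0.274 below it, so part of the 0.52 comes from BI882370. As a hypothesis, the departure of P4B may go with ligase binding, which P4B_me lacks, but the weaker inhibition by P4B_me and the chemistry of the compounds stay open.

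The genes that set P4B apart from both BI882370 and P4B_me fall into a lower and a higher part. Of 305 lower genes 95.4%, and of 246 higher genes 84.6%, also differ between dabrafenib, with its lower MAPK score, and BI882370 in the same direction, but this decides nothing, since the BI882370 libraries also stand in the choice of the genes. Between dabrafenib and vemurafenib, which share no library with that choice, 91.5% of the lower genes differ in that direction, against 50.9% of all tested genes, which is consistent with stronger pathway inhibition by P4B, and 80.1% of the higher genes, against 49.1%, which leaves this explanation open for that part. GC content or transcript length is argued against, since with that trend removed and the replicate block 99.7% of 300 lower and 92.6% of 242 higher genes still pass in both comparisons, and 99.3% and 88% without the block, where the median difference from BI882370 went from −0.366 to −0.374 and from 0.325 to 0.283. Without any 1 P4B library the median difference from BI882370 stayed at 95.6% (lower) and 94.6% (higher) or more of its size. This decides nothing on a single library, since all P4B libraries chose the genes.

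ATF4 target genes, which serve amino acid synthesis, fell less against DMSO with dabrafenib (−0.656) than with trametinib (−1.031), a difference of 0.376 in the mean of 11 genes, 5 of them higher with dabrafenib and 6 not past the threshold, whereas 12 endoplasmic reticulum chaperone genes differed by −0.051 (95% interval −0.104 to 0.001). Scaling and a single library are argued against for these genes: the difference was 0.393 with median-of-ratios rescaling and at least 0.347 on leaving out 1 library (without trametinib replicate 1). Dabrafenib lay 0.188 (0.126 to 0.25) above P4B, less above P4B_me (−0.74 against DMSO) and more above BI882370 and vemurafenib, all with higher MAPK scores. The 11 genes leave out ATF3, which was lower (−0.71). So weaker pathway inhibition by dabrafenib than by trametinib and an effect apart from the MAPK pathway stay open.

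For each of the 16 comparisons the 6 libraries were also split in the 10 possible ways into 3 and 3, which cannot give a share under 0.05. In each comparison only 1 split, the real one, gave as many changed genes. The real counts were 10502 for P4B, 9216 for P4B_me, 10483 for BI882370, 11136 for dabrafenib, 10373 for vemurafenib and 11197 for trametinib against DMSO, where the highest other split gave 1 for P4B and 0 for the others. Between compounds they were 4429 for P4B against P4B_me, 1102 against BI882370, 4813 against dabrafenib, 1148 against vemurafenib and 5343 against trametinib, 3987 for P4B_me against BI882370, 4769 for BI882370 against dabrafenib, 191 against vemurafenib, and 5347 and 223 for dabrafenib against vemurafenib and trametinib. The highest other split gave 1 for dabrafenib against trametinib and 0 for the rest. Like the real split, 4 of the splits part all 3 same-number pairs, and the other 6 part 1 pair.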
